A study of Mus musculus with 11 samples.

How the data were processed

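Total RNA was taken from dorsal keratinocytes of K5-myrAkt mice, a transgenic line with activated Akt in cells that express keratin 5, and measured on single-channel Affymetrix expression arrays. The cells had been incubated with an antibody against CD34 and parted with magnetic beads, and the labels give 5 arrays of CD34+ cells and 6 arrays of CD34- cells. CD34 is a surface marker of stem cells in the bulge of the mouse hair follicle. Groups and replicate numbers were taken from the sample titles. The labels give no age, hair cycle stage, scan date or batch, and they do not say whether the arrays came from separate mice, so p-values measure the spread between these samples only.

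The authors deposited 1 value per probe set and array, on the log2 scale, made with MAS5 per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. The log2 scale was read from the values: after conversion to linear signal, the mean after trimming 2% of the probe sets from each end lay between 500.002 and 500.004 on all 11 arrays, so that the arrays had a common mean before further use. The values were used as deposited, without a further normalization between arrays. No detection calls were used here, so a low value was read as dim and not as absent. The number of arrays limits the precision. The median standard error of a log2 difference was 0.187.

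The table holds 45101 probe sets, of which 64 are controls. Probe sets were named through the platform annotation, whose gene identifiers were matched to the names of the GRCm38.p6 annotation for 34754 probe sets. 34945 probe sets had 1 gene symbol, 932 had several and 9160 that are not controls had none. Only those with 1 symbol were used, and they stand for 18193 genes. A gene was represented by its probe set with the highest mean log2 signal over all arrays. Of the 55 named and called genes with another probe set that passed the brightness filter, 33 had at least 1 such probe set that was not called or turned direction, and 22 had none. The dimmest 40% of genes by that mean were left out, and 10916 genes were tested, all with a mean log2 signal of at least 6.59. For other probe sets the filter left out the dimmest 40% of probe sets with 1 symbol instead. Some that passed it had a mean under 6.59, such as that of Prf1 at 6.15.

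CD34+ and CD34- arrays were compared for each gene with limma 3.58.1 in R 4.3.3, using a linear model on the log2 values, empirical Bayes moderation with an intensity trend (prior degrees of freedom 5.5) and Benjamini-Hochberg adjustment. Every adjusted p of a gene comes from this limma model, and a gene was called at an adjusted p under 0.05. The adjusted p of another probe set comes from the same model fitted to every probe set by itself, adjusted over those that passed. Differences are CD34+ minus CD34- on the log2 scale. Gene lists for follicle and epidermal cells, other cell types of skin, the cell cycle, signalling, matrix, metabolism and stress were fixed before the data were examined, and Cd34 is in none of them. The 38 lists with at least 5 tested genes were tested with camera from limma at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with a correlation estimated for each list and the fry rotation test were run as alternatives.

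Genes to be named were chosen by a rule fixed before the data were examined. It takes Cd34, Akt1 and Krt5, then the 8 highest and 8 lowest differences among genes called with all arrays and with each array left out in turn. It adds the 3 members with the smallest p in the direction of each called list, the member with the smallest p of each other list if it was called, and the 2 brightest members of each list of another cell type. The rule named 90 genes. A further 64 genes were named after their values were seen, mostly to complete small counts, and are marked in the text. Other genes were examined in the same way and then left unnamed to keep the text short, so the named genes are no sample of all genes.

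Alternatives fixed before the data were examined were quantile normalization, equal medians, other brightness filters, an offset before log2, the mean of probe sets, every probe set by itself, other moderation, array weights, an exact rank-sum test, stricter thresholds, the replicate number as a block, and leaving out each array. Alternatives added after the data were examined were the actin ratio of each array as a covariate, fits without CD34+ arrays 1 and 2 or 1 to 3, values under the 40th percentile of each array raised to it, and 10000 random lists matched on brightness. The actin ratio is the log2 signal of the 3-prime actin control probe set minus that of the 5-prime actin control probe set, which rises as RNA or labelled copies become shorter.

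The limma and camera steps were tested on simulated data with the means and spreads of the 10916 tested genes, 5 against 6 arrays. Of 50 genes each changed 1.5-fold, 2-fold, 4-fold and 8-fold, 28.0%, 66.0%, 100% and 100% were called in the right direction. Of 162 calls, 4 (2.5%) fell on unchanged genes. A planted list of 20 genes had a camera p of 4.24e-37 and an unchanged list of 20 genes had a camera p of 0.903. Genes were drawn independently of each other, with the same spread in both fractions. The simulation therefore does not show how camera behaves with correlated genes or with a wider spread on CD34+ arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading and drawing.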

Results

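The expression of 18193 named genes was measured in CD34+ and CD34- keratinocyte fractions from the back skin of K5-myrAkt mice, with 5 CD34+ and 6 CD34- arrays. The comparison asks how hair follicle cells that carry the bulge marker CD34 differ from CD34- cells of the same transgenic skin. The cell type label of the CD34- samples also names follicle stem cells, whereas the study's design text does not, so what those cells are is left open here. No fraction from mice without the transgene was analysed here, so the comparison does not measure an effect of Akt.

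Cd34, the gene the cells were sorted on, had a mean log2 signal of 11.83 ± 1.17 (SD, n = 5) on CD34+ arrays and 4.20 ± 1.57 (SD, n = 6) on CD34- arrays, with no overlap between the arrays. The log2 difference was 7.63 (SE 0.69, limma adjusted p = 1.21e-05). On CD34- arrays Cd34 lay within the dimmest 33.9% of probe sets, so the size of this difference depends on dim values. With values under the 40th percentile of each array raised to it, Cd34 was at least 55.1-fold higher on CD34+ arrays. Akt1, whose probe sets cannot be assumed to separate the transgene from the endogenous gene, gave different values by probe set. The brightest showed a log2 difference of 0.00 (SE 0.20, adjusted p = 1), the next -0.61 (adjusted p = 0.0145) and a dimmer one 0.61 (adjusted p = 0.237). Krt5, the source of the transgene's promoter and a keratin of basal keratinocytes, had a difference of -0.07 (SE 0.13, adjusted p = 0.705), and of -0.44 after quantile normalization.

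Between the fractions, 1350 genes were higher and 1347 lower in CD34+ cells, which is 24.7% of the 10916 tested. At least a 2-fold difference was seen for 525 higher and 231 lower genes. The highest differences were those of Pdzrn4 (6.53, SE 0.63), the small proteoglycan gene Ogn (5.71, SE 0.31), the interleukin 31 receptor gene Il31ra (5.58, SE 0.59), Itm2a (5.01, SE 0.48), Sphkap (4.85, SE 0.41), the growth factor gene Fgf18 (4.83, SE 0.52) and the proteoglycan gene Aspn (4.71, SE 0.54), besides Cd34. On CD34- arrays Pdzrn4, Ogn, Il31ra and Fgf18 were under the 40th percentile on all 6 arrays, and with values raised to that percentile they were at least 36.8-fold, 24.7-fold, 12.7-fold and 10.9-fold higher in CD34+ cells. The 8 lowest differences included those of the T cell list members Cd7 (-3.85, SE 0.40), Cd3g (-2.69, SE 0.78) and Gzmc, a granzyme gene (-2.31, SE 0.30). Outside that list they were those of Ms4a4b (-2.50, SE 0.61), Cd163l1 (-2.43, SE 0.66), the perforin gene Prf1 (-2.32, SE 0.54), Trgv1 (-2.28, SE 0.47), a variable segment of the T cell receptor gamma chain, and the nucleoside diphosphate kinase gene Nme1 (-2.31, SE 0.14, adjusted p = 3.16e-07). Several of these were dim in CD34+ cells. Values lay under the 40th percentile on 4 of 5 CD34+ arrays for Cd7 and Cd163l1, on 3 for Ms4a4b and Trgv1 and on 1 for Cd3g and Prf1. Raised to that percentile, they gave differences of -2.37 for Cd7, -1.34 for Cd163l1, -1.69 for Ms4a4b, -1.51 for Trgv1, -2.05 for Cd3g and -1.77 for Prf1. CD34+ array 1 carried much of the differences of Cd3g and Cd163l1, where their log2 signals were 3.40 and 2.00 against 6.81 to 9.18 and 6.12 to 6.61 on the other CD34+ arrays. Without it the differences were -1.74 and -1.56, and their ranks from the lowest went from 2 to 12 and from 4 to 21. The other probe set of Prf1 that passed the brightness filter went the opposite way (0.92, adjusted p = 0.106), and that of Nme1 differed by -0.76 (adjusted p = 0.00529). On its brightest probe set Nme1 fell from a mean log2 signal of 13.00 ± 0.12 (SD, n = 6) to 10.69 ± 0.30 (SD, n = 5).

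**Figure D1:**
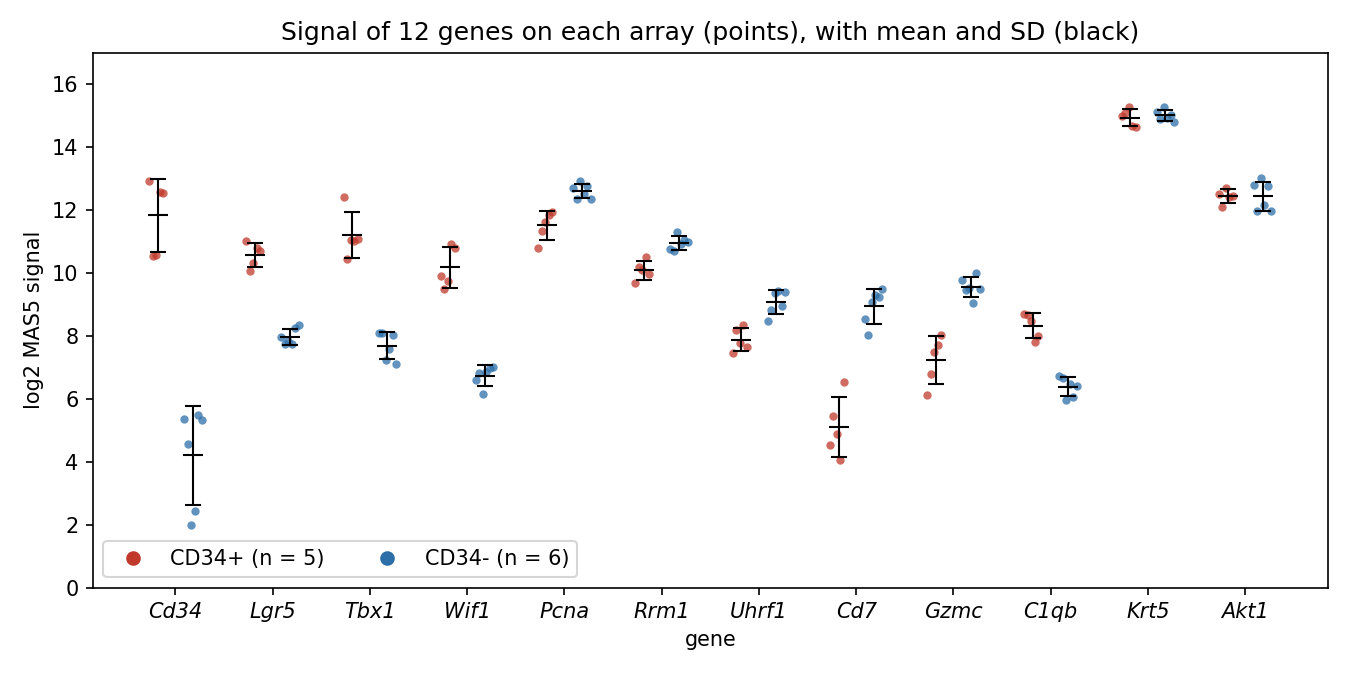
Log2 MAS5 signal (vertical axis) of 12 genes (horizontal axis) on each CD34+ array (red points, n = 5) and each CD34- array (blue points, n = 6), with the mean and SD in black. The arrays of the fractions do not overlap for Cd34, Lgr5, Tbx1, Wif1, Pcna, Rrm1, Uhrf1, Cd7, Gzmc and C1qb, and overlap for Krt5 and Akt1.

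Genes known from hair follicle bulge stem cells were higher in CD34+ cells as a group. Of 19 tested, 17 rose and none fell, with 18 higher when adjusted over the list alone, and the median log2 difference was 1.89. The members with the smallest p were Lgr5 (2.60, SE 0.19, adjusted p = 2.02e-06), a Wnt target and marker of cycling follicle stem cells, the secreted Wnt inhibitor gene Wif1 (3.45, SE 0.27, adjusted p = 4.24e-06) and the transcription factor gene Tbx1 (3.51, SE 0.30, adjusted p = 9.08e-06). Among members chosen after their values were seen, the transcription factor genes Lhx2 (4.02, SE 0.48), Sox9 (1.16, SE 0.23) and Nfatc1 (1.02, SE 0.21) rose with no overlap between the fractions on their brightest probe sets. The other Sox9 probe sets that passed the filter were not called (0.31, adjusted p = 0.592, and 0.64, adjusted p = 0.336), nor was 1 of Nfatc1 (0.23, adjusted p = 0.633). Krt15, a keratin of the bulge and of basal epidermis chosen in the same way, differed by 0.47 (SE 0.16, adjusted p = 0.0467). That call was lost on leaving out any of 9 arrays (highest adjusted p = 0.0953), and its difference was 0.02 after quantile normalization and -0.04 with the actin ratio described next as a covariate. The camera adjusted p of the list was 6.16e-15, and adjusted p = 0.221 with an estimated correlation. The actin 3-prime to 5-prime ratio, a measure of RNA length, was higher on every CD34+ array than on any CD34- array (3.95 ± 0.99, SD, n = 5, against 2.43 ± 0.19, SD, n = 6, on the log2 scale). With that ratio as a covariate the list had an adjusted p of 4.58e-17, while 7 of its 17 called genes were called by themselves and their median standard error went from 0.27 to 0.36.

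Signalling genes of the follicle moved in both directions. The BMP pathway list was called higher (median 0.53, adjusted p = 0.0294, and adjusted p = 0.384 with an estimated correlation). Of its 17 tested genes 6 rose and 2 fell, the same counts as when adjusted over the list alone. Those with the smallest p that rose were the secreted BMP antagonist gene Grem1 (3.81, SE 0.35), the signal transducer gene Smad1 (0.80, SE 0.12) and Id4 (1.19, SE 0.21). The ligand genes Bmp4 (-1.20, SE 0.24) and Bmp2 (-0.72, SE 0.25, chosen after its value was seen) fell, Bmp2 with a call lost on leaving out any of 8 arrays (highest adjusted p = 0.104) and a difference of 0.02 with the actin ratio as a covariate. The other probe sets of Smad1 that passed the brightness filter gave differences of -0.27 (adjusted p = 0.616) and -0.36 (adjusted p = 0.101), and 1 of Id4 gave 0.76 (adjusted p = 0.0525). The BMP list lost its call in the fits without CD34+ array 4 (adjusted p = 0.0514) and without CD34- array 2 (adjusted p = 0.0587), with no brightness filter (0.0627), with the brightest 40% of genes (0.17, median 0.11) and with the mean of probe sets (0.206). Its median was 0.31 after quantile normalization and 0.25 with the actin ratio as a covariate, both with the call kept.

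The Wnt, Notch, TGF-beta and hair germ lists were not called, although single members differed. The following members, apart from Wif1, Fzd2, Dll1, Ccn2 and Gli2, were named after their values were seen. Of 8 Wnt antagonist genes 4 rose and none fell, the same counts as when adjusted over the list alone (camera adjusted p = 0.0858). These were Wif1, Dkk3 (2.22, SE 0.32), Sfrp1 (1.29, SE 0.24) and Sfrp4 (1.25, SE 0.40), and the list was called without CD34+ array 1 (adjusted p = 0.0337), without CD34+ arrays 1 and 2 (adjusted p = 0.0328) and with the actin ratio as a covariate (adjusted p = 0.00515). The Wnt antagonist list overlaps with the bulge list, Wif1 being in both, so its counts are not fully separate evidence. Of 20 Wnt ligand and receptor genes 3 rose and 6 fell, with 5 and 7 when adjusted over the list alone (median -0.18, adjusted p = 0.7). The ligand genes Wnt3a (-1.03, SE 0.28), Wnt4 (-0.83, SE 0.16), Wnt7b (-0.99, SE 0.18), Wnt10a (-0.65, SE 0.22) and Wnt16 (-0.72, SE 0.25) fell, while the receptor gene Fzd2 (1.89, SE 0.31) rose. In the Notch list 3 genes rose and 3 fell, also when adjusted over the list alone (median -0.10, adjusted p = 0.726). The ligand genes Dll1 (-1.27, SE 0.19) and Jag2 (-1.10, SE 0.19) and the target gene Hes1 (-0.54, SE 0.19) fell, and Jag1 (1.03, SE 0.35), Hey1 (1.59, SE 0.24) and Dtx1 (0.80, SE 0.23) rose. In the TGF-beta list 7 genes rose and 3 fell, also when adjusted over the list alone (median 0.16, adjusted p = 0.128). Ccn2 (3.22, SE 0.29), Tgfb2 (2.71, SE 0.34) and Inhba (2.23, SE 0.33) were among those that rose, and Smad2 (-0.77, SE 0.14) and the receptor genes Tgfbr2 (-0.84, SE 0.16) and Tgfbr3 (-0.92, SE 0.29) fell. In the hair germ list 4 genes rose and 2 fell, with 5 and 2 when adjusted over the list alone (median 0.54, adjusted p = 0.123, and 0.048 with the actin ratio as a covariate). The hedgehog pathway genes Gli2 (1.68, SE 0.22), Gli3 (1.05, SE 0.18) and Shh (1.18, SE 0.38) and the transcription factor gene Runx1 (1.13, SE 0.19) rose, and Eda2r (-0.61, SE 0.17) and Wnt10a fell. The calls of Sfrp4, Wnt10a, Wnt16, Hes1, Jag1, Dtx1, Tgfbr3 and Shh were each lost when some single array was left out, with highest adjusted p of 0.0842, 0.0889, 0.0993, 0.0955, 0.0886, 0.0543, 0.074 and 0.0731. Without CD34+ array 1 the differences of Wnt10a, Jag1 and Tgfbr3 were -0.42, 0.57 and -0.57, and without CD34+ array 2 that of Shh was 0.77. With the actin ratio as a covariate Jag1 differed by -0.02 and Tgfbr3 by 0.19. Other probe sets that passed the filter were not called for Sfrp1 (0.66 and 0.37), Wnt4 (-0.39), Jag1 (0.60 and 0.17), Jag2 (-0.68), Smad2 (-0.31) and Runx1 (0.49 and 1.01).

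Genes of DNA replication were lower in CD34+ cells as a group. Of 30 tested, 14 fell and none rose, with 17 lower when adjusted over the list alone, and the median log2 difference was -0.61. Examples were Pcna, the sliding clamp of DNA polymerase (-1.09, SE 0.19, adjusted p = 0.00172), the ribonucleotide reductase gene Rrm1 (-0.86, SE 0.16, adjusted p = 0.00211) and Uhrf1, which acts in maintenance DNA methylation (-1.19, SE 0.22, adjusted p = 0.00219), none of which overlapped between the fractions. The camera adjusted p was 7.43e-06, and adjusted p = 0.405 with an estimated correlation. The 25 mitosis genes were not called as a list (median -0.10, adjusted p = 0.117), with 5 lower and none higher, and 3 lower when adjusted over the list alone. The mitosis list was called lower after quantile normalization (adjusted p = 0.0227), without CD34+ array 1 (0.0499), without CD34+ arrays 1 and 2 (0.0237), without CD34- array 6 (0.0478), with no brightness filter (0.00801) and with the actin ratio as a covariate (0.0138). Their member with the smallest p was the spindle gene Prc1 (-0.70, SE 0.12). Of 12 cell cycle inhibitor genes 7 fell and none rose, the same counts as when adjusted over the list alone, and the list was not called (median -0.61, adjusted p = 0.053). It was called in 5 of 11 fits without 1 array and in 4 of 12 other settings with the preset correlation, among them no brightness filter (0.00801). Its lead member Btg1 differed by -0.55 (SE 0.13), while its other probe sets that passed the filter gave 0.40 (adjusted p = 0.039) and -0.78 (adjusted p = 0.0644). With the actin ratio as a covariate, the median of the 14 replication genes went from -0.81 to -0.55 and their median standard error from 0.20 to 0.29. By themselves 0 of the 14 were called, while the list had a median of -0.37 and kept a camera adjusted p of 0.00117. Against the CD34- mean, the median of all 30 genes was -1.05, -0.32, -0.55, -0.55 and -0.48 on CD34+ arrays 1 to 5. On CD34- arrays it was -0.27 to 0.22. CD34+ array 2, with an actin ratio of 4.56, had the smallest drop, so the drop did not rise steadily with the ratio.

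Genes of the upper epidermal layers and of tissue handling also differed. Of 28 suprabasal and cornified envelope genes 11 rose and 4 fell, with 14 higher and 5 lower when adjusted over the list alone (median 0.47, adjusted p = 0.0229, and adjusted p = 0.599 with an estimated correlation). Spink5, a serine protease inhibitor gene (0.98, SE 0.10), and the late cornified envelope genes Lce1a1 (1.18, SE 0.20) and Lce1c (1.54, SE 0.27) rose. The 4 that fell, named after their values were seen, were Krt1 (-0.82, SE 0.29), Calm4 (-0.87, SE 0.21), Casp14 (-1.22, SE 0.31) and Dsg1b (-0.88, SE 0.29), and the calls of Krt1 and Dsg1b were lost on leaving out single arrays (highest adjusted p = 0.101 and 0.0877). Without CD34+ array 1 Krt1 differed by -0.54. Krt10, also named after its value was seen, rose by 0.36 (SE 0.12), but its difference was -0.10 after quantile normalization and its call was lost on leaving out any of 7 arrays (highest adjusted p = 0.1). This list lost its call without CD34+ array 3 (adjusted p = 0.0932) without CD34+ arrays 1, 2 and 3 (adjusted p = 0.306, median 0.13) and with no brightness filter (0.0627). Its median was 0.25 after quantile normalization, 0.25 with the actin ratio as a covariate, 0.28 with the brightest 40% of genes and 0.31 with array weights, with the call kept in each. Of 24 immediate early genes, which respond within minutes to stress or tissue dissociation, 8 fell and 3 rose, with 11 lower and 3 higher when adjusted over the list alone (median -0.46, adjusted p = 0.0294, and adjusted p = 0.599 with an estimated correlation). Ier2 (-1.06, SE 0.19), Fosb (-1.06, SE 0.25) and Btg2 (-0.76, SE 0.19) fell. Egr3 (0.49, SE 0.14), Gadd45b (0.96, SE 0.23) and Ier3 (0.60, SE 0.20), named after their values were seen, rose, Ier3 with a highest adjusted p of 0.0886 on leaving out 1 array. Other probe sets that passed the filter were not called for Gadd45b (0.17 and 0.09) and Btg2 (-0.83), and that of Casp14 gave 0.46 (adjusted p = 0.195). The immediate early list was no longer called without CD34+ array 4 (adjusted p = 0.0906), CD34+ array 5 (0.0731), CD34- array 1 (0.0634) or CD34- array 2 (0.0587), nor with the brightest 40% of genes (0.164).

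T cell genes were lower in CD34+ cells. Of 9 tested, 7 fell and none rose, with 8 lower when adjusted over the list alone, and the median was -1.48 (camera adjusted p = 2.74e-04, and adjusted p = 0.378 with an estimated correlation). Besides Cd7, Gzmc and Cd3g, the T cell receptor complex gene Cd3e (-1.48, SE 0.32) and Thy1 (-1.20, SE 0.26) fell. With the actin ratio as a covariate Cd3g turned to 0.48, and without CD34+ array 1 it differed by -1.74. Without CD34+ arrays 1 and 2 the list had an adjusted p of 7.72e-05. The list of antigen presenting and myeloid cells was not called (median 0.65, adjusted p = 0.0541), with 8 of 18 genes higher and 2 lower, and 9 and 3 when adjusted over the list alone. After quantile normalization its median lay 1.09 and 1.29 above the CD34- mean on CD34+ arrays 4 and 5, but only 0.20 to 0.29 above it on CD34+ arrays 1 to 3, against -0.33 to 0.25 on CD34- arrays. The complement gene C1qb (1.95, SE 0.24, adjusted p = 1.64e-04) and the class II antigen presentation gene H2-Aa (0.95, SE 0.25) rose, as did Ctss (0.63, SE 0.20) and the macrophage growth factor receptor gene Csf1r (1.20, SE 0.34, named after its value was seen). The 2 that fell, also named after their values were seen, were Ptprc, which encodes the pan-leukocyte marker CD45 (-1.81, SE 0.40), and Coro1a (-1.07, SE 0.30). Csf1r was no longer called without CD34+ array 5 (adjusted p = 0.0506), Coro1a without CD34- array 6 (adjusted p = 0.05) and Ctss without any of 6 arrays (highest adjusted p = 0.0707). Other probe sets that passed the filter were not called for Csf1r (0.97 and 0.36), Coro1a (-0.88) and, in 1 case, H2-Aa (0.23). The myeloid list was called higher in 5 of 11 fits without 1 array, without CD34+ arrays 1 and 2 (adjusted p = 4.15e-04), with array weights (6.81e-04) and with the actin ratio as a covariate (adjusted p = 3.73e-12). The T cell list had a median of -0.83 and an adjusted p of 0.00515 with that covariate, and the median of its 7 called genes went from -1.48 to -1.02, with 1 of them called by itself.

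Genes that are strong in fibroblasts were higher in CD34+ cells as a group. Of 13 tested, 10 rose and none fell, the same counts as when adjusted over the list alone, and the median was 2.31 (adjusted p = 3.06e-10, and adjusted p = 0.121 with an estimated correlation). Ogn, the type VI collagen gene Col6a2 (3.94, SE 0.35) and the type I collagen gene Col1a2 (3.49, SE 0.26) had the smallest p, and Sparc, named after its value was seen, rose by 4.17 (SE 0.52). Without CD34+ arrays 1 and 2 the list had an adjusted p of 2.19e-10, and with the actin ratio as a covariate 2.41e-12. The smooth muscle and pericyte list was called with 5 of 6 genes higher, also when adjusted over the list alone (median 0.93, adjusted p = 0.00628, and adjusted p = 0.221 with an estimated correlation). These were Synpo2 (3.66, SE 0.43), Cspg4 (0.90, SE 0.23), Smtn (0.97, SE 0.25), Mylk (0.83, SE 0.29) and Acta2 (2.05, SE 0.54, named after its value was seen), and the call of Mylk was lost on leaving out any of 8 arrays (highest adjusted p = 0.0986). All but Synpo2 overlapped between the fractions. The log2 signal of Acta2 was 10.78, 11.79, 8.24, 11.10 and 8.52 on CD34+ arrays 1 to 5. On CD34- arrays it was 7.55 to 8.47, so CD34+ arrays 3 and 5 lay at or near that level. Of 10 melanocyte genes Kit fell (-1.33, SE 0.24) and Mitf rose (1.42, SE 0.33), also when adjusted over the list alone, and the list was not called (median -0.25, adjusted p = 0.676). The other passing probe sets of Cspg4 (0.60) and Mitf (1.07) were not called. Mitf overlapped between the fractions, with a log2 signal of 11.3 and 11.5 on CD34- arrays 1 and 2. It was 10.1 to 10.6 on CD34- arrays 3 to 6 and 11.5 to 13.2 on CD34+ arrays. Schwann cell genes were not called (median 0.08, adjusted p = 0.909), with 2 of 6 higher and 1 lower, and 2 and 2 when adjusted over the list alone. Sebaceous gland genes were not called either (median -0.24, adjusted p = 0.779), with 1 of 14 lower, and 0 when adjusted over the list alone.

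**Figure D2:**
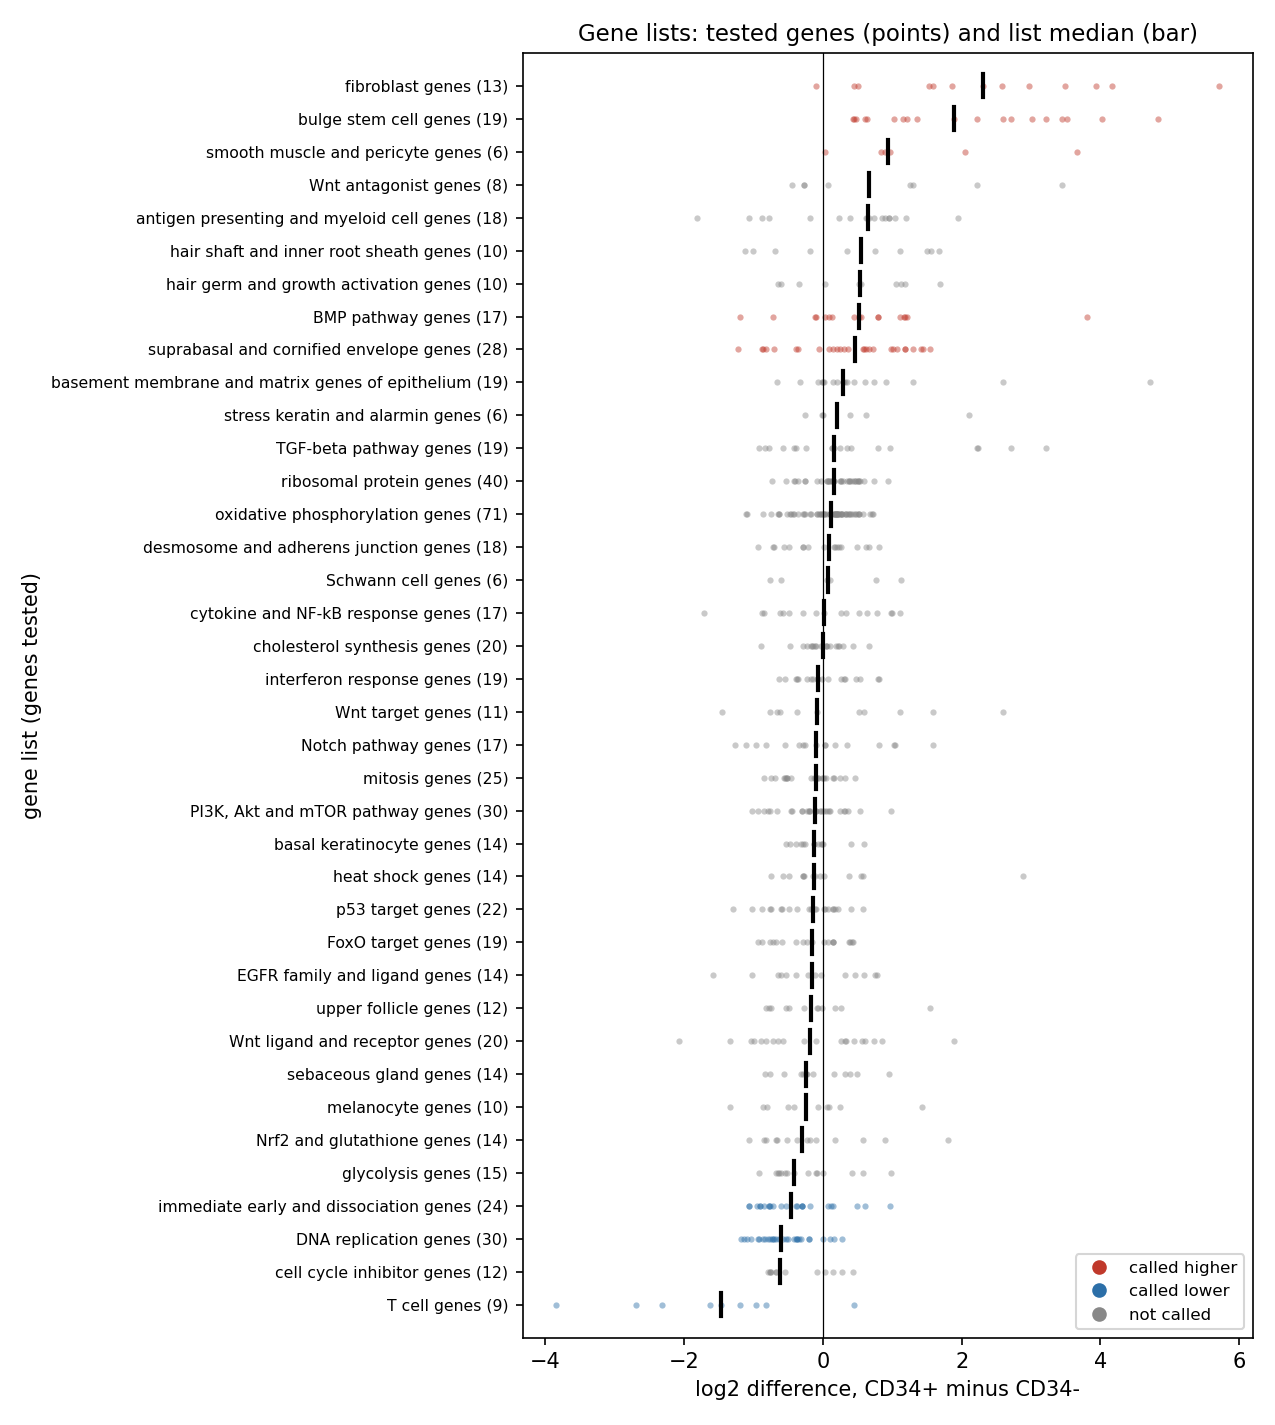
Log2 difference between CD34+ and CD34- arrays (horizontal axis) of each tested gene (points) in the 38 tested lists (vertical axis, number of genes in brackets), with the list median as a black bar and lists called by camera at the preset correlation in red (higher) or blue (lower). The fibroblast list has the highest median (2.31) and the T cell list the lowest (-1.48).

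The remaining lists were not called, with adjusted p from 0.0518 to 0.969 over all 30 of them. The basement membrane (0.0518) and ribosomal protein (0.053) lists were each called higher in 5 of 11 fits without 1 array, and the glycolysis list lower in 3. In 12 other settings with the preset correlation, the basement membrane list was called in 7, the ribosomal list in 2 and the glycolysis list in 4. The basement membrane list was called without CD34+ arrays 1 and 2 (adjusted p = 0.0328), while the ribosomal median of 0.16 was -0.03 after quantile normalization (adjusted p = 0.607). With no brightness filter the glycolysis, p53 target and PI3K lists were called lower (0.00462, 0.0143 and 0.0204). The median and the mean, or either and the direction of the test, differed in sign for the heat shock, Wnt target, interferon response, desmosome, cytokine and cholesterol synthesis lists. In the PI3K, Akt and mTOR list (30 genes, median -0.11, adjusted p = 0.241) 1 gene rose and 5 fell, also when adjusted over the list alone, among them Akt2 (-0.76, SE 0.13). Of 19 FoxO targets 1 rose and 4 fell, with 1 and 5 when adjusted over the list alone (median -0.15, adjusted p = 0.348). Of 14 basal keratinocyte genes 1 rose and 2 fell, also when adjusted over the list alone (median -0.13, adjusted p = 0.348, and 0.0376 with the actin ratio as a covariate), and the integrin gene Itga6 fell (-0.53, SE 0.10). Of 15 glycolysis genes (median -0.42, adjusted p = 0.053) 8 fell and 3 rose, the same counts as when adjusted over the list alone. The phosphofructokinase gene Pfkl fell by 0.91 on the log2 scale (SE 0.16), while Hk2 (0.99, SE 0.20), Aldoc (0.57, SE 0.14) and Pfkm (0.42, SE 0.14), named after their values were seen, rose, Pfkm with a highest adjusted p of 0.0888 on leaving out 1 array. Other probe sets that passed the filter were not called for Akt2 (-0.17 and 0.13) and, in 1 case, Pfkl (0.44). The cytokine gene Il33 fell by 1.72 (SE 0.27) and the stress keratin gene Krt6a rose by 2.10 (SE 0.52) on the log2 scale. For Krt6a the fractions overlapped and CD34- arrays 1 and 2 stood apart. Its log2 signal was 12.01 and 11.61 on them, 9.44 to 9.69 on CD34- arrays 3 to 6 and 11.61 to 13.90 on CD34+ arrays.

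**Figure D3:**
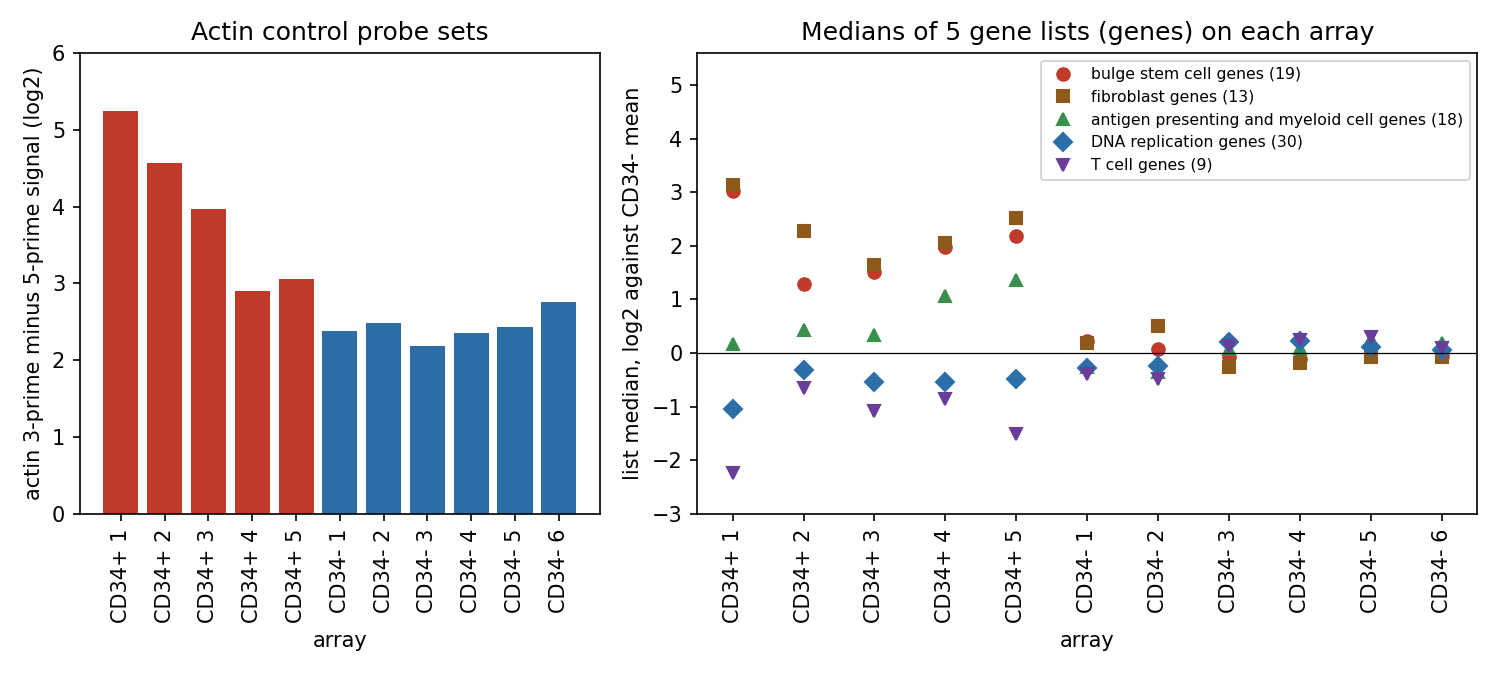
Left, log2 signal of the 3-prime minus the 5-prime actin control probe set on each array (bars, CD34+ red, CD34- blue), and right, median of 5 gene lists on each array as the log2 difference from the CD34- mean (number of genes in brackets). The actin ratio is 5.25, 4.56, 3.97, 2.91 and 3.06 on CD34+ arrays 1 to 5 and 2.19 to 2.76 on CD34- arrays, and bulge genes lie highest on CD34+ array 1 (3.03).

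Other probe sets that passed the filter and were called in the same direction gave differences over 1.5 times larger or smaller for Itga6 (-1.04), Col6a2 (2.39), Fzd2 (1.16), Mylk (2.02), Egr3 (2.13) and, in 1 case, H2-Aa (1.52).

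CD34+ arrays differed more among themselves than CD34- arrays did. The mean rank correlation with the other arrays of the same fraction was 0.857 and 0.87 for CD34+ arrays 1 and 2, 0.895 to 0.903 for CD34+ arrays 3 to 5 and 0.932 to 0.938 for CD34- arrays. CD34+ arrays 3 to 5 correlated more highly with the CD34- arrays (0.913 to 0.921) than with the other CD34+ arrays. Leaving out CD34+ array 1 or 2 gave 2479 or 2273 called genes, and leaving out any single CD34- array 1865 to 2230. Without CD34+ arrays 1 and 2, 908 genes were higher and 914 lower, and 823 and 808 of these had been called with all arrays in the same direction. With the actin ratio as a covariate, 96 genes were higher and 30 lower. Over the 2697 called genes the difference with the covariate was a median of 0.646 times that without it, and the median standard error went from 0.19 to 0.27.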

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

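The tests of the actin ratio and of called lists under other splits were chosen only after the result was seen.

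Most single arrays that stood apart from their group were CD34+ array 1. Over 316 groups of values (each named gene, and 4 quality measures, in each fraction), 28 had an array whose gap to its neighbour passed Dixon's 95% limit. Of the 28, 19 were CD34+ array 1. About 15.8 would pass by chance if the groups were independent and fixed beforehand. They were not, as 64 of the genes were named after their values were seen and all genes share the same 11 arrays. The 28 can therefore not be weighed against that number. Gaps are given as a share of the group's range. On CD34+ array 1 the signal was higher than on the other CD34+ arrays for Fgf18 (0.792), Cryab (0.822), Ccn2 (0.834), Jag1 (0.895), Hey1 (0.743), Hk2 (0.724) and Col1a1 (0.831). On the same array it was lower for the lymphocyte genes Ms4a4b (0.765), Cd163l1 (0.894) and Prf1 (0.803), and for Il33 (0.848), Btg2 (0.729), Kit (0.839), Lpl (0.858), Erbb3 (0.919), Mbp (0.842), Bmp2 (0.861), Tgfbr2 (0.742) and Kcnj16 (0.854). Elsewhere the gaps were those of Pdzrn4 (0.75), Sphkap (0.626) and Gli3 (0.68) on CD34- array 4, Foxn1 (0.729), Col8a2 (0.667) and Lum (0.734) on CD34- array 3, Pfkl (0.754) and Col16a1 (0.78) on CD34+ array 3, and Col6a3 (0.723) on CD34+ array 2.

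The control probe sets and the probe sets with no or several gene symbols also carried a signal. The actin ratio was 1.52 higher on CD34+ arrays (two-sided exact permutation test over 462 splits, p = 0.00216, the smallest it can give), while the same ratio for Gapdh differed by 0.16 (p = 0.342 in the exact test). Of 4030 probe sets with no or several gene symbols, 1071 were higher and 176 lower in CD34+ cells, 1247 in all. Tested together with the named probe sets, 24.1% of them were higher against 12.7% of named probe sets of like brightness, and after quantile normalization 13.1% against 5.5%. The shares of lower probe sets were 3.9% against 6.8%, and 4.5% against 9.1% after quantile normalization. The median log2 difference of all named genes went from 0.81 in the dimmest of 5 equal groups by brightness to -0.09 in the brightest, and from 0.21 to -0.03 after quantile normalization.

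RNA integrity was weighed as the source of the group differences. Chance is an unlikely source of the number of genes if the arrays are independent samples, which the labels do not state. The labelled split gave 2697, the highest of the other 99 splits drawn gave 322, and 1 of 100 splits, the labelled one, gave as many. Only 100 of 462 splits were drawn. This count does not bear on RNA integrity, as the actin ratio parts the same arrays. For bulge genes the actin ratio as a covariate left the list called at the preset correlation (camera adjusted p = 4.58e-17). Without the covariate the list was not called at an estimated correlation (camera adjusted p = 0.221). On CD34+ arrays 1 to 5 the bulge median lay 3.03, 1.29, 1.52, 1.98 and 2.19 above the CD34- mean. The actin ratios of these arrays were 5.25, 4.56, 3.97, 2.91 and 3.06. The 17 called members kept a median of 0.821 times their difference, and 7 of them were still called by themselves, with a median standard error of 0.36 in place of 0.27. The called DNA replication genes kept a median of 0.710 times their difference by the same measure. On another measure, their median difference with the covariate was 67.6% of that without it. For both lists the shares that come from RNA integrity and from the fraction cannot be told apart, because the actin ratio overlaps nowhere between the fractions. A lower replication rate in CD34+ cells stays open and was not tested otherwise.

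The number of called lists is no evidence by itself. The labelled split called 8 lists, 34 of 100 splits called as many, and the highest of the others called 12, so chance cannot be excluded for that number. For single lists, the camera p was as small in 1 of 100 splits for the bulge and the fibroblast list (the labelled one in each case), in 2 for T cell and for smooth muscle and pericyte genes, in 10 for DNA replication and for BMP pathway genes, in 31 for suprabasal genes and in 33 for immediate early genes. For the T cell list another split gave a smaller p than the labelled one (3.01e-06 against 2.88e-05), as for the smooth muscle and pericyte list (0.000327 against 0.000826). The lowest p of the other splits drawn was 6.25e-14 for the bulge list, against 1.62e-16, and 1.76e-10 for the fibroblast list, against 1.61e-11. These shares rest on 100 of 462 splits and are not adjusted over the 38 lists, so they exclude chance for no single list.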

How the results depend on the processing

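The actin covariate, the fits without several CD34+ arrays and the values raised to the 40th percentile were chosen only after the data were examined. Cd34 kept its direction and its call in each setting that tested it by itself, which the brightest 40% of genes did not (7.19 to 7.96 on leaving out 1 array, 5.78 with values raised to the 40th percentile). The main counts were 2697 genes (1350 higher, 1347 lower) and 8 lists. Leaving out 1 array gave 1865 to 2789 genes, 969 to 1370 higher, 896 (without CD34- array 4) to 1419 lower and 6 to 13 lists (13 without CD34- array 6). The mean of probe sets gave 1728 genes (949 higher, 779 lower), the brightest 40% of genes 743 higher, 1187 lower and 5 lists, an adjusted p under 0.01 1004 (548 and 456), at least 2-fold 756 (525 and 231), the actin covariate 126 (96 and 30) and 14 lists, the offset 13 lists, camera with an estimated correlation 0 lists and fry, which does not compare a list with other genes, 18. Stricter thresholds give fewer calls by construction; for the others, the brightness filter included, the cause was not tested. Quantile normalization gave 1068 higher and 1152 lower, of which 970 and 1022 were called in the same direction with the deposited values.

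The arrays were not treated as paired by replicate number, as the labels do not say that a shared number pairs samples. Deviations of same-numbered arrays correlated at 0.16, 0.02, 0.19, 0.13 and 0.04 across genes, so not every pair passed a limit of 0.1. Of 5 CD34+ arrays, 1 correlated best with its own number. These values do not settle whether the arrays are paired. With the replicate number as a block 2025 genes were called (1044 higher, 981 lower), and as a random block 2976.

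The directions that turned in results called in at least 1 of the settings compared, with the cause not tested, were these. They cover the named genes only, and genes examined and then left unnamed had turned too. With the actin covariate: Cd3g 0.48, Mbp 0.0018, Krt15 -0.0444, Bmp2 0.0184, Jag1 -0.0215, Tgfbr3 0.19, Kcnj16 0.0247 and the hair shaft list (median -0.55, adjusted p = 0.0266). After quantile normalization: Krt10 -0.10. With the mean of probe sets: Tgfbr3 0.35 and Zap70 -0.0475. On other probe sets: Prf1 0.92, Smad1 -0.27 and -0.36, Btg1 0.40, Ctnnd1 0.34, Pfkl 0.44, Akt2 0.13, Mbp 0.53, Casp14 0.46 and Col4a6 0.0093. Array signal over background limits what dim genes show.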

Other observations

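All families below, and the tests of direction between lymphoid genes and myeloid or fibroblast genes, were chosen only after the data were examined, while the second lists of T cell, macrophage and fibroblast genes were written before their values were seen, while the members named from them, and Col6a3 and Fn1, were chosen afterwards.

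Of 9 gene families tested with camera, collagens were called higher (23 genes, median 0.38, adjusted p = 0.0148, and adjusted p = 0.486 with an estimated correlation). Of them 8 rose and 3 fell, with 9 and 4 when adjusted over the family alone. The fibroblast list holds 5 of the 8 that rose, so the call largely restates that list. The fibril collagen gene Col5a2 (2.98, SE 0.34) and Col8a2 (3.52, SE 0.33) rose beside Col1a2 and Col6a2, whereas Col16a1 (-0.80, SE 0.13), Col23a1 (-1.87, SE 0.59) and the basement membrane gene Col4a6 (-0.66, SE 0.21) fell, the last pair with calls lost on leaving out single arrays (highest adjusted p = 0.0665 and 0.0778). A first version of the potassium channel family wrongly held the non-coding RNA gene Kcnq1ot1 and was called, and that gene was removed after the result was seen. Potassium channel genes were then not called as a family (14 genes, adjusted p = 0.0824, but 0.0438 without CD34+ arrays 1 and 2), with 6 higher, among them Kcnma1 (3.22, SE 0.40) and Kcnk2 (2.45, SE 0.52), and Kcnj16 lower (-0.97, SE 0.33, highest adjusted p = 0.0837 on leaving out 1 array). Without CD34+ array 1 Col23a1 differed by -1.15 and Kcnj16 by -0.56. Of 5 insulin-like growth factor binding protein genes, Igfbp5 (3.86, SE 0.34) and Igfbp7 (2.76, SE 0.25) rose and Igfbp3 (-0.65, SE 0.12) fell, but the other passing probe set of Igfbp5 was not called (0.41, adjusted p = 0.653) and that of Igfbp3 gave -1.44. Other passing probe sets were not called either for Col23a1 (-0.83 and -1.27), Col4a6 (0.0093), Kcnj16 (-1.17) and, in 1 case, Kcnma1 (1.32). The other families had adjusted p from 0.143 to 0.9. Lists with fewer than 5 tested genes had medians over their named genes of 1.02 (mast cell), 0.94 (dermal papilla), 0.60 (skeletal muscle), 0.49 (endothelial), 0.09 (adipocyte) and 0.04 (erythroid), which after quantile normalization were 0.51, 0.30, 0.05, 0.16, -0.20 and -0.43. Xist had a log2 signal of 13.61 to 14.60 on the 11 arrays and the Y-linked gene Eif2s3y 7.79 to 11.07. Eif2s3y was 10.54 to 11.07 on CD34+ arrays 2 and 3 and CD34- arrays 3 and 4, and 7.79 to 9.25 on the others. Same-numbered arrays thus differed in level for numbers 2 and 4.

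The T cell list was called lower in CD34+ cells, though not with an estimated correlation (camera adjusted p = 0.378). The myeloid list was not called with all arrays. Among called members 0 of 7 T cell genes and 8 of 10 myeloid genes were higher (two-sided Fisher's exact test, p = 0.00226, over genes, which are not independent). That is a count of the members that had shown the pattern and so no separate evidence. A lower share of keratinocytes in the CD34- fraction would raise markers of every other cell type there. The fibroblast list cannot decide on that share, because fibroblasts that carry CD34 would pass the sort whatever the share. After quantile normalization its median lay 1.59 or more above the CD34- mean on every CD34+ array and at most 0.48 above it on CD34- arrays. That of the T cell list lay at -0.76 or below on CD34+ arrays and at -0.45 or above on CD34- arrays. A lower share of keratinocytes stays open. The bound set beforehand was not met, as a second list of 12 macrophage genes (5 higher and 2, Cd83 and Cx3cr1, lower) had a median of 0.68 after quantile normalization, but a camera p of 0.186 (as deposited 0.0247, and p = 0.0725 with an estimated correlation), and macrophages or other antigen presenting cells in the CD34+ fraction stay open. T cells in the CD34- fraction, which the bead sort on CD34 would not remove, may account for the pattern but stay open too, as a second list of 9 T cell genes had 1 lower (Itgae, -1.69, not called on its other passing probe set) and 1 higher (Zap70, 1.12), a median of -0.83 (0.06 above the CD34- mean on CD34+ array 4) and a camera p of 0.144 (-1.04 and 0.0493 after quantile normalization, and p = 0.464 with an estimated correlation as deposited).

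The median of the fibroblast list lay higher on every CD34+ array than on any CD34- array, although its members Col6a3 (0.44), Fn1 (-0.10) and Vim (0.51) were not called, and dermal fibroblasts, some of which carry CD34 and would pass the sort, are a candidate source. Of a second list of 12 fibroblast genes 5 rose and Tnxb fell. After quantile normalization its camera p was 0.0102, and it lay at a median of 0.85 above the CD34- mean on CD34+ array 1 and 0.52 over CD34+ arrays 2 to 5, between the bounds of 1 and 0.5 set for and against that source. Col1a1, a main product of dermal fibroblasts, had a log2 signal of 9.06 on CD34+ array 1. It was 4.91 to 5.61 on CD34+ arrays 2 to 5 and 4.04 to 6.19 on CD34- arrays. For Lum these values were 7.68, 2.57 to 5.18 and 2.43 to 5.29. Both were too dim to be tested, and lay under the 40th percentile on 4 of 5 CD34+ arrays. On CD34- arrays this held on 5 (Col1a1) and 6 (Lum), so CD34+ arrays 2 to 5 cannot be judged from them. Col3a1 was higher on all CD34+ arrays, with 10.19, 7.09 to 8.70 and 2.22 to 6.98. So was Dcn, with 8.12 to 8.59 against 6.11 to 7.37 on CD34- arrays. Pdgfra was 7.98 to 9.52 on CD34+ arrays 1 to 4, 6.56 on CD34+ array 5 and 5.65 to 7.34 on CD34- arrays. Dcn and Pdgfra were chosen after their values were seen and are outside the named genes. Expression of Col1a2, Col6a2 and Sparc by the CD34+ keratinocytes themselves stays open, as no test here separates it from other cells.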
